A study of Homo sapiens with 8 samples.

How the data were processed

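RNA was measured on Clariom S Human arrays, 1 array per culture, in 8 cultures of Hep3B, a line grown from a human hepatocellular carcinoma. Per the labels' protocols, 3 cultures received valeric acid at 850 µM and RNA was extracted after 48 h. Another 5 cultures were controls, 2 labelled batch 1 and 3 labelled batch 2, and the labels give no batch for the treated cultures. Per the series' design text, the replicates were grown and harvested independently.

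The deposited values are log2 expression values per probe set, made by the authors with SST-RMA at gene level, per the file headers. The submitters' processing notes name Affymetrix Expression Console and RMA, and their versions are not given in the sources used here. RMA corrects background, brings the arrays to one distribution and summarises the probes of each probe set. The values were deposited rounded to 2 decimals, and no header or label records an adjustment for batch. The authors' deposited table also holds a signed fold change per probe set (another unit, written as minus the inverse ratio where treated arrays were lower) and p-values with false discovery rates from the authors' own comparison. The test behind those p-values is not given in the sources used here. A second deposited table held the same log2 values, equal within 1e-09 for all 21448 probe sets. Coordinates are those of the authors' annotation for the hg38 build, per the file headers, and span the whole transcript cluster.

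Probe sets were named through their RefSeq accessions and the reference's current symbols. Accessions named 18039 probe sets, a current symbol 683 and an older symbol 137. No gene was named from 1042 probe sets with several symbols, 966 with neither a RefSeq nor an Ensembl transcript, 551 not placed on a chromosome, 16 with a symbol absent from the reference, 10 with accessions of several genes and 4 whose symbol had been turned into a date. These 2589 probe sets stayed in the fit and out of the gene counts. The 18859 named probe sets stood for 18453 genes. For the 383 genes with several named probe sets, the brightest over the 8 arrays represented the gene. Among their 406 other probe sets, 80 passed the threshold together with the representative, 15 of them in the opposite direction. Another 159 did not pass although the representative did.

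Valeric acid was compared with control by limma's lmFit and eBayes on the deposited log2 values of all 21448 probe sets, 3 arrays against 5, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all probe sets, and genes with an adjusted p under 0.05 were counted. A fit with 3 groups (treated, control batch 1, control batch 2) compared the control batches with each other and the treated arrays with each batch. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 33 lists, with camera's estimated correlation and fry as alternatives. Counts within a list are given over all genes tested and adjusted over the list alone.

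The 33 lists were fixed before the data were examined, as were the samples, the tests, the rule for named genes and most of the other settings. They cover histone deacetylases, genes reported to rise or to fall under their inhibitors, E2F targets and DNA replication, mitosis, cyclin-dependent kinase inhibitors, replication-dependent histones and neuronal REST targets. Others cover hepatocyte functions, complement and coagulation, drug and bile acid metabolism, oncofetal markers, cholesterol synthesis, fatty acid synthesis, PPAR-alpha targets with fatty acid oxidation, short-chain acid catabolism, and receptors and transporters of short-chain acids. The rest cover the integrated stress response, heat shock, interferon response, NF-kB, immediate early genes, metallothioneins, NRF2 targets, hypoxia with glycolysis, respiratory chain subunits, epithelial-mesenchymal transition, apoptosis, ribosomal proteins, and markers of fibroblasts, blood cells, endothelium and squamous epithelium.

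Genes were named by rule: the 12 highest and the 12 lowest log2 differences among genes past the threshold whose treated arrays all lay above, or all below, every control; the up to 4 members of each list with the smallest p; and always HDAC1, HDAC2, HDAC3, CDKN1A, E2F1, E2F3, CCND1, ALB and AFP. Some genes that the rule takes are not reported here. The rule also allowed for the 5 highest and 5 lowest genes past the threshold between control batches, of which there were none. It took 153 genes. Where a count of 5 or fewer list members is completed with a gene outside the rule, that gene was chosen after its values were seen.

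Other settings chosen then were quantile normalization applied again, subtraction of array medians, leaving out probe sets below the median level, a trended robust prior, array weights, a minimum change of 1.2-fold, the mean of a gene's probe sets, each control batch alone, batch as a random block, the replicate number as a block, and leaving out each array. Chosen after seeing the data were a spread taken within batches, a spread taken from the treated arrays alone, and camera on genes above the median level. All 56 splits of the 8 arrays into 3 and 5 were refitted. The files give no detection calls, so no probe set was removed as background, and the number of arrays limits the precision. In simulated data for 18453 genes with 200 changed, the fit recovered 31.8% of genes changed by 0.5 on the log2 scale. It recovered 91% of those changed by 1 and 100% of those changed by 2, with 7 false calls among 156. In the deposited data 9919 genes passed, which makes the adjusted threshold less strict than in the simulation. The simulated shares are therefore not the shares recovered in the data. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.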

Results

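Expression was profiled in Hep3B cells, a human hepatocellular carcinoma line that keeps many liver functions. The comparison asks which genes change when these cells are exposed to valeric acid, a short-chain fatty acid described as an inhibitor of histone deacetylases (HDACs). There were 3 treated cultures (850 µM, 48 h) and 5 controls, of which 2 came from batch 1 and 3 from batch 2. Array medians were 6.21 to 6.23 on the log2 scale in the treated arrays and 6.07 to 6.08 in the controls. Across probe sets, treated arrays correlated with each other at r = 0.9932 to 0.9952 and with controls at r = 0.9439 to 0.9494. All differences below are treated minus control on the log2 scale, with the standard error (SE) of the fit, and levels are mean ± SD with n = 3 treated and n = 5 control arrays.

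The gene with the highest difference was C1QL1, a secreted C1q-related protein of the nervous system (chromosome 17, 44959693 to 44968276, hg38, probe set TC1700010856.hg.1). It rose from 5.46 ± 0.15 to 13.57 ± 0.15, a difference of 8.11 (SE 0.117) or 276.9-fold (adjusted p = 3.29e-13). TXNIP, an inhibitor of thioredoxin, rose 157.5-fold (difference 7.30, SE 0.216), and DHRS2, a short-chain dehydrogenase, rose 106.4-fold (6.73, SE 0.145). The other 9 genes with the highest differences rose 69.4-fold to 97.1-fold, of which KIF5C (4.02) and KCNH7 (4.14) had control levels below 4.2, the lower quartile of all probe sets, where an array understates folds. Control levels lay below it in 7 of the 68 named genes that rose. Those other 9 genes with the highest differences included genes of neuronal transport and synapses (KIF5C, SYT11, KCNH7, TUBB2B) and the G protein subunit GNG7. They also included the protease inhibitor SERPINE2, the lysosomal protein LAMP3 and the galectin LGALS1.

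The gene with the lowest difference was SLC22A9, an organic anion transporter of liver (chromosome 11, 63369789 to 63410294, probe set TC1100007892.hg.1). It fell by 8.57 (SE 0.160), from 13.28 ± 0.05 to 4.71 ± 0.44, which is 379.7-fold lower (adjusted p = 1.53e-12). FABP1, the liver fatty acid binding protein, was 378.6-fold lower (difference -8.56, SE 0.157), and SLCO1B3, a hepatic uptake transporter, was 223.8-fold lower (-7.81, SE 0.165). The smallest fold among the 12 was 51.2-fold, for the fibrinolysis inhibitor CPB2. Others were ANGPTL8, a secreted regulator of lipoprotein lipase, the histidine-degrading enzyme HAL, the bile acid receptor NR1H4 (FXR) and the complement protease MASP1, with TM4SF4, GPER1 and TNFSF4. Several of these treated levels lie near or below that quartile.

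**Figure D1:**
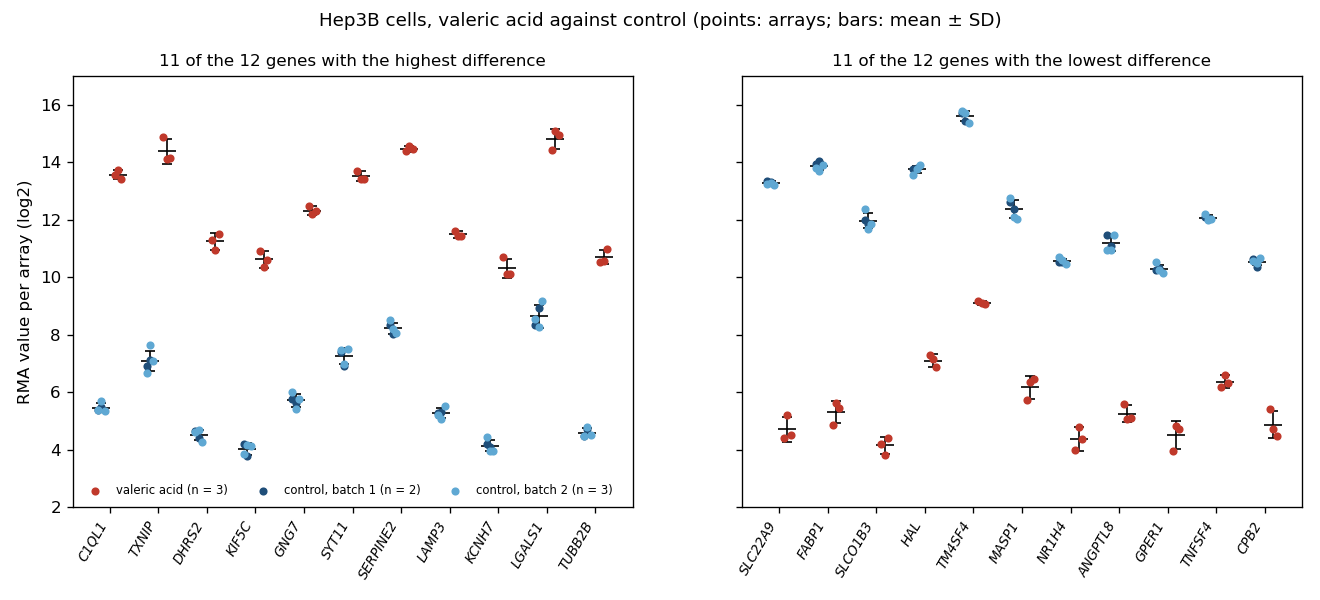
Log2 RMA values (vertical axis) on each array for 11 of the 12 genes with the highest (left) and 11 of the 12 with the lowest (right) difference, with mean ± SD per group; red points are valeric acid (n = 3), dark and light blue points are control batches 1 (n = 2) and 2 (n = 3). No treated array overlaps a control in these genes, C1QL1 lying at 13.57 against 5.46 and SLC22A9 at 4.71 against 13.28.

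Of 18453 genes tested, 5237 were higher and 4682 were lower in valeric acid. The share past the threshold ran from 21.4% at control levels below 4 to 77.2% at 10 to 12. Single members past the threshold are therefore common in any list, and their count alone does not set a list apart. A change of at least 2-fold was called in 2339 higher and 1911 lower genes, and of at least 16-fold in 103 and 89. In 51% of genes every treated array lay above, or every treated array below, all controls, where chance gives 3.57%. The authors' deposited table lists 7700 probe sets at a false discovery rate under 0.05, 4128 higher and 3572 lower. Its signed folds run from -450.55 to 294.33. Counted in probe sets rather than genes, 11056 passed the threshold of the limma fit. Against control batch 1 alone 7951 genes passed the threshold, and against batch 2 alone 8525. Genes called against both batches in the same direction numbered 7913, with 4299 higher and 3614 lower. Both comparisons share the treated arrays, and the batch means were nearly equal in the deposited values. The count is therefore no separate support. Of the genes past the threshold, 52.8% were higher, and 49.31% with quantile normalization applied again. After subtraction of each array's median only 39.85% were higher. The median difference of all genes was 0.00733 before that subtraction, which shifts it by -0.148 and so moves the typical gene below 0. With batch as a random block, and the treated arrays as a block of their own, 17260 genes passed. The correlation within blocks was -0.49, which lowers the standard error of the treated mean, so that count is not comparable with the others. The labels give no batch for the treated cultures, and each labelled batch holds controls only, so no comparison within a batch can be made.

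Genes widely reported to rise under HDAC inhibitors rose as a group. Of 18 measured, 13 rose and 2 fell, and the counts adjusted over the list alone were the same, 13 and 2 (camera adjusted p = 9.99e-06; adjusted p = 0.097 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 4.34 ± 0.17 to 9.15 ± 0.03, or 27.9-fold (difference 4.80, SE 0.116, adjusted p = 8.64e-12). The members that fell were the histone H2BC12 (-1.72) and the sodium channel subunit SCNN1A (-1.64). Of 15 genes reported to fall under such inhibitors, 10 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0139; adjusted p = 0.409 with an estimated correlation). TYMS, thymidylate synthase, was 24.4-fold lower (-4.61, SE 0.133), CCND1, cyclin D1, 6.13-fold lower (-2.62, SE 0.126), and CTPS1, a CTP synthase, 5.81-fold lower. Against that direction, thymidine kinase TK1 rose 4.61-fold (2.21, SE 0.154), CDK1 rose by 0.68 and TOP2A by 0.39. TYMS, RRM2, TK1 and E2F1 also belong to the list of E2F targets and replication genes. BIRC5, TOP2A, CCNB1, CDK1 and AURKA also belong to the mitosis list. The results of these lists are therefore not separate evidence.

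The zinc-dependent HDAC genes themselves went both ways, as did genes over the whole array (9919 of 18453 past the threshold). HDAC5 rose 5.46-fold (2.45, SE 0.126), HDAC3 rose 3.56-fold (1.83, SE 0.099) and HDAC1 rose 1.86-fold (0.90, SE 0.109), whereas HDAC7 was 2.01-fold lower (-1.0, SE 0.126). HDAC2 was 12.88 ± 0.13 in treated and 12.91 ± 0.11 in control arrays (-0.03, SE 0.108, adjusted p = 0.849). In all, 4 of the 11 rose and 3 fell, and 4 and 3 adjusted over the list alone (camera adjusted p = 0.597).

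DNA replication genes fell, and mitotic genes went both ways. Of 30 E2F targets and replication genes, 23 fell and 3 rose, and the same 23 and 3 were counted adjusted over the list alone (camera adjusted p = 6.84e-06; adjusted p = 0.150 with an estimated correlation). The replicative helicase subunit MCM7 was 4.77-fold lower (-2.25, SE 0.113) and the transcription factor E2F3 was 3.75-fold lower (-1.91, SE 0.145). E2F1 was 4.85 ± 0.43 against 4.83 ± 0.28 (adjusted p = 0.927), a level below the median probe set. The members that rose were TK1, CCNE1 (0.52) and GINS2 (0.48). Replication-dependent histone genes fell in 24 of 35 cases and rose in 3, and in 25 and 4 adjusted over the list alone (camera adjusted p = 0.00053; adjusted p = 0.478 with an estimated correlation). H2AC4 fell by 1.88 (SE 0.134), H3C2 by 1.18 and H4C1 by 1.38, while H2BC14 (1.44), H3C8 (0.55) and H1-3 (0.35) rose. These histone genes are close copies that can share probes. Among 28 mitosis genes 12 rose and 8 fell, the same adjusted over the list alone (camera adjusted p = 0.755), but 9 rose and 10 fell with array medians subtracted. The mitotic transcription factor FOXM1 fell by 1.55 (SE 0.097) and the kinases AURKA by 1.05 and AURKB by 0.72, while the kinase CDK1 rose by 0.68 (SE 0.107).

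Among 7 cyclin-dependent kinase inhibitors, 3 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.834). CDKN2A, which encodes p16 and ARF, fell from 14.83 ± 0.29 to 9.65 ± 0.50, or 36.3-fold (-5.18, SE 0.213). Its chromosome 9 neighbour CDKN2B fell 7.53-fold (-2.91, SE 0.171) and CDKN1B (p27) fell by 0.88 (SE 0.203). The members that rose beside CDKN1A were CDKN1C (0.89) and CDKN2D (0.80).

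Genes of hepatocyte identity fell together. Of 30 hepatocyte proteins and transcription factors, 24 fell and none rose, and 24 fell and 1 rose adjusted over the list alone (camera adjusted p = 9.1e-09; adjusted p = 0.122 with an estimated correlation). Fibrinogen FGB was 37.3-fold lower (-5.22, SE 0.159) and the asialoglycoprotein receptor subunit ASGR2 10.7-fold lower (-3.42, SE 0.128). Albumin (ALB) was 17.63 ± 0.01 in treated and 17.79 ± 0.02 in control arrays (-0.16, SE 0.090, adjusted p = 0.156), near the highest value on any array, 18.37. ALB passed the threshold with array medians subtracted (-0.31, adjusted p = 0.0108), with quantile normalization applied again (-0.25, adjusted p = 0.0482) and with a trended robust prior (-0.16, adjusted p = 0.0166). Of 27 complement and coagulation genes, 21 fell and 2 rose, and 22 and 2 adjusted over the list alone (camera adjusted p = 2.11e-07; adjusted p = 0.097 with an estimated correlation). Coagulation factor F7 was 35.8-fold lower (-5.16, SE 0.126), protein C (PROC) 15.1-fold lower and complement factor CFB 10.1-fold lower. Complement C3 went against that direction and rose by 1.27.

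Hepatic drug and bile acid metabolism held a few deep falls among many dim genes. Of 22 measured, 8 fell and 1 rose (CYP3A5, 0.39), the same adjusted over the list alone, and 13 passed no threshold (camera adjusted p = 0.0139; adjusted p = 0.122 with an estimated correlation). The sulfotransferase SULT2A1 was 39.0-fold lower (-5.28, SE 0.124), the alcohol dehydrogenase ADH4 32.7-fold, the export pump ABCC2 29.1-fold and the glucuronosyltransferase UGT2B7 12.5-fold lower. The treated level of ADH4, 3.66, lay in the lower quartile of probe sets, where an array understates folds. Oncofetal and progenitor markers fell in 11 of 19 cases and rose in 3, the same adjusted over the list alone (camera adjusted p = 0.00783; adjusted p = 0.374 with an estimated correlation). The RNA-binding proteins LIN28B and IGF2BP1 were 24.5-fold and 25.6-fold lower, DLK1 was 19.8-fold lower and AFP, alpha-fetoprotein, was 3.46-fold lower (-1.79, SE 0.124). The cholangiocyte keratin KRT19 rose 18.6-fold (4.21, SE 0.126), and KRT7 (0.80) and PEG10 (0.57) also rose.

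Genes of sterol and fatty acid synthesis fell nearly as a block. Of 23 cholesterol synthesis and uptake genes, 22 fell and 1, the kinase PMVK, rose by 0.90. The same 22 and 1 were counted adjusted over the list alone (camera adjusted p = 4.44e-12; adjusted p = 0.097 with an estimated correlation), with a median of -2.13. HMGCS1 was 13.8-fold lower (-3.78, SE 0.143), CYP51A1 12.1-fold, squalene epoxidase SQLE 6.55-fold and EBP 5.83-fold lower. Of 15 lipogenesis genes 12 fell and 1, the acetyl-CoA carboxylase ACACB, rose by 1.74, the same adjusted over the list alone (camera adjusted p = 8.75e-06; adjusted p = 0.10 with an estimated correlation). The acyltransferase GPAM was 35.3-fold lower (-5.14, SE 0.193), the desaturase FADS2 29.9-fold (-4.90, SE 0.095), the elongase ELOVL6 13.2-fold and the lipase PNPLA3 12.9-fold lower.

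All 8 metallothioneins, small metal-binding proteins, rose, also adjusted over the list alone (camera adjusted p = 2.49e-06; adjusted p = 0.122 with an estimated correlation). MT1X rose 55.3-fold (5.79, SE 0.245), MT1A 32.0-fold, MT1G 19.1-fold and MT1E 8.59-fold, though these paralogs are alike enough to share signal. MT1X and MT1F also belong to the list of genes induced by HDAC inhibitors. Of 17 NRF2 targets 10 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0309; adjusted p = 0.310 with an estimated correlation). GCLC, which makes the first product of glutathione synthesis, rose 6.55-fold (2.71, SE 0.117), while ABCC3 (-2.81) and OSGIN1 (-0.98) fell. The 5 members past no threshold were NQO1 and HMOX1 (both -0.15), PGD, AKR1B10 and FTL. Among genes above the median level alone, the list's camera adjusted p was 0.102. Immediate early genes rose in 9 of 15 cases and fell in 1, MYC (-0.96), with the same counts adjusted over the list alone. Their camera adjusted p was 0.0441 (adjusted p = 0.374 with an estimated correlation), but 0.0915 without treated replicate 1, 0.063 without batch 2 control replicate 1, 0.07 against control batch 1 alone and 0.171 among genes above the median level. The phosphatase DUSP1 rose 13.9-fold (3.80, SE 0.169) and JUNB 2.48-fold.

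The mesenchymal and neuronal lists held more rises than falls. Of 24 genes of epithelial-mesenchymal transition and matrix, 13 rose and 3 fell, and 14 and 3 adjusted over the list alone (camera adjusted p = 0.00783; adjusted p = 0.150 with an estimated correlation). The transcription factor SNAI1 rose 29.7-fold (4.89, SE 0.188), SNAI2 10.1-fold, vimentin (VIM) 5.52-fold and TGFB1 4.88-fold. MMP14 (-2.60), FN1 (-0.38) and ITGAV (-0.35) fell, and the epithelial cadherin CDH1, a member of the same list, rose by 1.02. Of 22 neuronal genes held down by REST outside neurons, 13 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.00783; adjusted p = 0.10 with an estimated correlation). STMN2 rose 15.5-fold (3.96, SE 0.120) to 7.91, from a control level of 3.95 in the lower quartile of probe sets, where an array understates folds. The potassium channel KCNH2 rose 6.36-fold to 7.80, while SYP reached 6.02 and UNC13A 4.35, both below the median probe set level of 6.17.

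**Figure D2:**
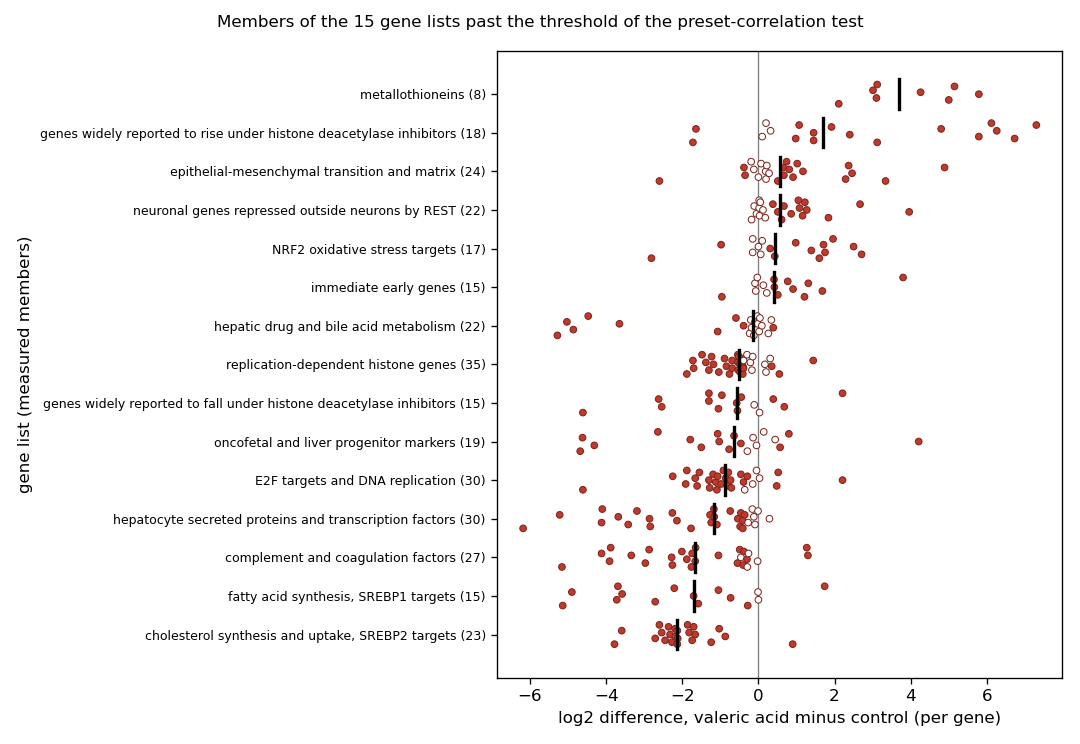
Log2 difference, valeric acid minus control (horizontal axis), of each measured member of the 15 gene lists past the threshold of camera's preset-correlation test, with the number of members in brackets; filled points have an adjusted p under 0.05 and black bars are list medians. Medians run from -2.13 for cholesterol synthesis to 3.69 for metallothioneins, and lists such as hepatic drug metabolism hold members near 0 beside members below -3.

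In total 15 of the 33 lists passed with camera's preset correlation of 0.01, 9 downward and 6 upward, and 0 passed with an estimated correlation. By fry, which asks whether a list's genes move one way on balance and compares them with no other genes, 30 passed.

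Markers of other cell types passed no camera test as lists, though single markers moved, as did 9919 of all 18453 genes. Of 11 fibroblast markers 5 rose and 1 fell, and 5 and 2 adjusted over the list alone (camera adjusted p = 0.666), with the proteoglycan LUM 6.66-fold higher (2.74, SE 0.120) and the receptor PDGFRB 4.97-fold lower. Of 13 blood cell markers 4 fell and none rose, the same adjusted over the list alone (camera adjusted p = 0.0789). Lysozyme (LYZ) stood at 14.16 ± 0.29 in the controls and was 42.2-fold lower in treated arrays. Of 10 endothelial markers 2 rose, ESAM by 1.70 and CLDN5 by 0.58, and of 10 squamous markers 2 rose, KRT17 by 1.31 and SFN by 0.72. The call of CLDN5 was lost without treated replicate 2 (adjusted p = 0.0621) and against control batch 1 alone (adjusted p = 0.0676). Both counts were the same adjusted over the list alone (camera adjusted p = 0.749 and 0.666). With array medians subtracted, 4 fibroblast markers rose and 4 fell, and 2 rose and 2 fell among both endothelial and squamous markers.

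The control batches showed no gene past the threshold between them by limma. Only 9 genes had an unadjusted p under 0.05, where chance gives 923, and the largest of these differences was CXCL10, a chemokine, at 0.58 (SE 0.164) higher in batch 2. With a trended robust prior, and with the control arrays alone, the count was also 0. Controls of different batches were closer to each other (r = 0.9975 to 0.9978) than controls of one batch (r = 0.9958 to 0.9968). The count of 0 is therefore not a measure of how far untreated batches differ.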

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

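Among 153 named genes, 1 had a control array far from the others: ORM1, an acute phase protein, read 12.39 in batch 2 control replicate 1 and 12.79 to 12.93 in the other controls, a gap of 0.741 of the range against a critical value of 0.71. Its treated mean was 7.30 (adjusted p = 3.83e-11 in limma). Chance alone sets 1 in 20 such groups apart, and 1.67% of all genes met the criterion.

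Among the 2589 probe sets that stand for no single gene, 1012 passed the threshold, 429 higher and 583 lower in valeric acid. They entered no gene count, and neither of these results was followed by a further test.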

How the results depend on the processing

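Chosen after seeing the data were the fits with the spread within batches (9239 genes) or of the treated arrays alone (8370 genes), and camera on genes above the median level (12 lists; the NRF2 and immediate early lists lost their call, and the REST list kept 3 members there, too few to test). Of 146 named genes past the threshold, 142 kept direction and threshold in every setting that tested them other than the random block; the other 4 were lost in at least 1 (RPL10A, RPL11, RPL14, CLDN5), and no named gene reversed. Leaving out 1 array gave 4983 to 5082 genes higher and 4313 to 4545 lower, 6487 to 7730 called against both batches, 0 between batches and 14 to 16 lists. Batch as a random block gave 8744 higher and 8516 lower, with a consensus correlation of -0.49 within blocks. The treated arrays, whose batch is not given, were taken as a block of their own. This fit assumes that controls of one batch differ more than controls of different batches, and applies the same correlation among the treated arrays. A negative correlation within a block lowers the standard error of its mean, so these counts are not comparable with those of the other fits. With a correlation estimated for each list 0 lists passed (the cause was not tested), and with fry, which compares a list with no other genes, 30 passed. The other settings gave 6910 (minimum change of 1.2-fold) to 10840 genes (array medians subtracted), and the second deposited table gave identical values. With the replicate number as a block 9969 genes and 15 lists passed, and deviations of same-numbered treated and control arrays correlated at -0.04 to 0.10, so the numbers were not taken to pair arrays; treated replicate 3 correlated best with a control of another number (0.07). Without detection calls, signal over background is unknown; genes below the median level were kept in the main count, and 7372 passed without them, since fewer were tested.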

Other observations

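The tests of the 2 explanations for the distances between controls, the ratio of batch to treated differences, the shares that rose at control levels of 6 to 8 and 8 to 10, and the count with the spread of the treated arrays alone, were chosen after seeing the data.

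Genes of fatty acid oxidation went both ways. Of 24 PPAR-alpha targets and oxidation genes, 10 rose and 6 fell, and 11 and 6 adjusted over the list alone (camera adjusted p = 0.219). CPT1A, which admits long-chain acids to mitochondria, rose 14.7-fold (3.87, SE 0.177), the acyl-CoA synthetase ACSL1 19.9-fold and the liver transcription factor CREB3L3 52.7-fold, beside the fall of FABP1. For short-chain acids, 6 of 18 catabolic genes rose and 7 fell, and 6 and 9 adjusted over the list alone (camera adjusted p = 0.502). With array medians subtracted, 4 of these catabolic genes rose and 10 fell. ACSM3, a medium-chain acyl-CoA synthetase that also takes short acids, rose 11.3-fold (3.50, SE 0.131), while MMAB fell by 2.81 and ACSS3, a propionyl-CoA synthetase, by 1.65. Of 12 receptors and transporters of short acids, 5 fell and none rose, the same adjusted over the list alone (camera adjusted p = 0.186), with SLC16A7 4.01-fold, SLC5A12 3.25-fold and HCAR3 3.15-fold lower.

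Several stress lists split. None differed from the other genes by camera, and over all 18453 genes 9919 passed the threshold. In the integrated stress response 10 of 23 rose and 8 fell (camera adjusted p = 0.749), with DDIT3 (CHOP) 7.67-fold and CHAC1 5.32-fold higher and NUPR1 23.1-fold lower. Among 12 heat shock genes 5 fell and 1 rose (camera adjusted p = 0.109), HSPH1 by -3.25 and DNAJB1 by 1.35. Of 24 interferon genes 9 rose and 4 fell (camera adjusted p = 0.219), IFI6 being 21.1-fold higher. Of 21 NF-kB and acute phase genes 4 rose and 6 fell (camera adjusted p = 0.666), with CXCL5 37.1-fold lower and BIRC3 3.52-fold higher. Hypoxia and glycolysis genes rose in 11 of 24 cases and fell in 4 (camera adjusted p = 0.206), but 11 and 8 with array medians subtracted. The hexokinases moved in opposite directions, HK1 higher, from a control level of 3.42 in the lower quartile of probe sets, and HK2 8.92-fold lower. The counts of these 5 lists were the same adjusted over the list alone.

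Of 25 respiratory chain subunits 11 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.0523), with NDUFB3 2.99-fold and SDHB 2.45-fold higher. That list passed without treated replicate 1 (0.0443), treated replicate 2 (0.0376) or batch 2 control replicate 2 (0.0484). Of 23 apoptosis regulators 7 rose and 6 fell, and 8 and 7 adjusted over the list alone (camera adjusted p = 0.834), the caspase-8 inhibitor CFLAR being 22.7-fold and BCL2L1 6.28-fold lower and BAK1 4.36-fold higher. Of 21 ribosomal proteins 2 rose and 3 fell, and 1 and 2 adjusted over the list alone (camera adjusted p = 0.776), but none rose and 6 fell with array medians subtracted; in the main fit RPS23 differed by -0.59 and RPL14 by -0.46. Median and camera direction differed in sign for the cyclin-dependent kinase inhibitors, the NF-kB genes, the apoptosis regulators, the ribosomal proteins and the fibroblast markers. Subtracting array medians turned the medians of the PPAR-alpha, stress response, NF-kB, apoptosis, ribosomal, endothelial and squamous lists below 0, none of them past the camera threshold, and left 8 that rose and 9 that fell in the stress response and 6 and 8 in apoptosis.

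The first pattern weighed is the size of the treated against control comparison, 9919 genes. Of 56 splits of the 8 arrays into 3 and 5, 1 gave as many, the real one, and the highest of the others gave 0. Every other split mixes treated arrays with controls, so the treated difference widens its spread and lowers its count. A chance arrangement of these arrays is therefore argued against as far as 56 splits allow, and is not excluded. A control batch difference left in the values is argued against. In no called gene did the batches differ by as much as treated and control arrays (highest ratio 0.739, median 0.0395). That evidence is limited, because a large batch difference widens the spread and makes a call less likely. A difference removed before deposit stays open. Genes called against both batches numbered 7913, and the split of batch 2 from the rest gave 0, as the prediction against it asked. Near-equal batch means (the third pattern) would give the first outcome either way. The second outcome comes from a split that mixes treated arrays with controls, so that prediction was wrongly set. A control spread lowered before deposit is argued against as the whole cause, since the spread of the treated arrays alone still gave 8370 genes. A separate batch of the treated cultures was not tested, since their batch is not given in the labels; the biological explanation, treatment, was therefore not compared within a batch.

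The second pattern is that genes dim in the controls rose more often than they fell: 66.2% of 2724 called genes with a control level below 6 rose, against 40.9% of 3156 above 10. Of 1852 called genes at 6 to 8, 58.7% rose (56.5 to 61, 95% Wilson intervals over genes, which are not independent). Of 2181 at 8 to 10, 48.2% rose (46.1 to 50.3). That fall argues against a floor of the array as the whole cause only if levels of 6 to 8 lie clear of it. This is not shown, since the median probe set lay at 6.17 and signal over background is unknown. The share fell further to 37% above 12 (34.4 to 39.6), where a floor is remote, though sorting by level could add there. The planned test pooled 6 to 10 and gave 53% of 4038 genes, inside the range set beforehand for a floor as the cause. Pooling hid the fall from 6 to 8 to 8 to 10, and that split was chosen after seeing the data. A share of a floor in the rises below 6 therefore stays open. Sorting by the control level itself could add to both ends, because with genes sorted by the average of the treated and control means 56.5% of those below 6 and 51.5% of those above 10 rose. That value lies between the bounds set for either outcome, so neither sorting nor a biological bias toward silent genes is excluded.

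The third pattern is that controls of different batches were closer than controls of one batch. The difference of the batch means had an SD of 0.0536 over probe sets, against 0.131 to 0.192 for the other 9 splits of the controls into 2 and 3, which is consistent with a batch adjustment before deposit that no label or header records. Batches that did not differ are argued against: exchangeable arrays would give deviations from the control mean correlating near -0.25 in all pairs, whereas same-batch pairs gave -0.92 to -0.37 and other pairs -0.07 to 0.02. Such an adjustment would lower the spread among controls, and the p-values given here with it; no biological explanation was tested.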
